A study of Homo sapiens with 14 samples.

How the data were processed

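The deposited table holds a count for each of 57736 Ensembl genes in each of 14 libraries, and all values are whole numbers. Per the labels' protocols, cell pellets were lysed in Tri-Reagent, RNA was purified on Direct-zol columns with DNase I treatment on the column, and libraries were made with the QuantSeq FWD 3' mRNA kit (Lexogen). Per the submitters' processing notes, Bowtie2, RSEM 1.2.31 and DESeq2 were used with the hg19 build; the notes give neither the versions of Bowtie2 and DESeq2 nor the order of the steps, and the gene annotation, rounding of the RSEM counts and read filters are not given in the sources used here. How the source cells were sorted and how the macrophages were derived is not given in the sources used here either. The plan had assumed expected counts that would need rounding, and no rounding was needed. All 14 columns were matched to samples by the labels, with 0 columns left over.

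Of the gene identifiers, 51959 were named by a table of gene names and 342 by GENCODE 29, while 5435, with 1.32% of all counts, kept their identifier. XIST, TSIX and Y-linked genes (474 identifiers) were left out before any test. Mitochondrial genes are absent from the table, so their share as a sign of damaged cells could not be computed. The reference at hand is a newer build than hg19, so no coordinates are given. Near-identical gene copies (FCGR3A and FCGR3B, class II genes, globins) and antisense genes can exchange reads, and their values are uncertain.

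The comparisons, samples, tests, thresholds, lists and alternatives were fixed before the data were examined, except where a test is named as chosen later. Genes with too few counts were removed with filterByExpr on the 4 groups, which kept 18543 (15945 of them named by a symbol). Libraries were scaled by TMM, dispersions estimated with estimateDisp, and genes tested with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit with robust=TRUE) under R 4.3.3, with 1 mean per group, all 14 libraries in 1 fit and no term for the patient. P values were adjusted by Benjamini-Hochberg over the genes tested, and a gene passed at an adjusted p under 0.05 with no minimum fold; "edgeR adjusted p" stands for this throughout. Groups without counts are given as a bound, with a floor of 3 counts over the group, and groups of 1 to 3 counts as a ratio with its counting interval. Log2 levels in the figures and correlations use a prior count of 2.

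Named genes follow a rule: S100A8, S100A9 and S100A12 always; then the 10 largest rises and 10 largest falls that passed, with at least 10 CPM in the higher group and the same sign in every patient (origin comparisons) or ranges that do not overlap (stage comparisons); then up to 4 genes of smallest p in each list described. Where fewer than 10 passed, the genes of smallest p fill up to 10 and are said not to pass. PLBD1 in source cells, LYNX1 and the genes of the closing part's marker lists were picked after their values were seen.

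The 30 fixed lists were S100 genes, granule proteins of neutrophil precursors, class II antigen presentation, immune suppression, blood monocyte markers, macrophage maturation, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, the endoplasmic reticulum and integrated stress response, immediate early genes, heat shock, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lipid efflux, lysosome, cell cycle, macrophage chemokines, and myeloid transcription factors. The others marked T cells, NK cells, B cells, platelets, erythroid cells, neutrophils, eosinophils with basophils and mast cells, dendritic cells, and epithelial cells with fibroblasts, or RNA quality (cytosolic ribosomal proteins, nuclear-retained and histone transcripts). Lists with at least 5 genes tested, 28 in all, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists by Benjamini-Hochberg. CCL3, CCL4, CCL5, CCL18, MRC1 and PECAM1 of these lists matched no identifier in the table.

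The whole analysis was tested on simulated data, with 100 genes changed by 2-fold and 100 by 4-fold in each comparison. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of scarcer genes is not covered. Without a patient term, 28% of the 2-fold and 80% of the 4-fold changes were found in M-MDSC against monocytes (71% and 94% with a block for the patient, 45% and 90% with DESeq2), and 58% and 85% in the macrophage comparison (78% and 94% with the block, 66% and 90% with DESeq2). For the monocyte origin, 38% of the 2-fold and 93% of the 4-fold changes between stages were found, and for the M-MDSC origin 39% and 96%. False calls made up 1.8% of the calls in source cells and 0% in macrophages, 3.5% and 8% with the block, and 4.4% and 4.9% between stages. For the stages all libraries were simulated from 1 mean per gene, without differences between patients, and 200 genes were changed. In the real data 65.3% and 67% of genes passed between stages, and the stages came from different patients. The simulated rates between stages may therefore not hold for the real data. A list moved by 0.5 log2 units was recovered by camera with either correlation and by fry, with 0 of 27 other lists called. The simulated genes were drawn independently, so this says nothing on false calls for lists whose genes vary together. In the real data the estimated correlation was 0.563 for cell-cycle genes in M-MDSC against monocytes.

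Library totals ran from 13624702 to 26412473 counts, higher in macrophages than in source cells. Common biological variation was 44.2% among source libraries and 29.3% among macrophage libraries, 38.5% and 13% once the patient was blocked. Deviations of libraries from their group means correlated between the 2 origins of the same labelled patient at 0.127 to 0.171 in source cells and 0.426 to 0.544 in macrophages, and were negative for every other pairing, so 7 of 7 labelled pairs matched. The chi-square per degree of freedom between replicates was at least 35.4, so no library is a copy of another.

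The alternatives were a block for the patient, DESeq2 1.42.0, limma-voom with the patient as a random effect (between stages, consensus correlation 0.407), DESeq2 size factors or library totals for scaling, no filter or at least 5 CPM in 3 libraries, robust=FALSE, fits of the compared groups alone, all libraries thinned to the smallest total, a minimum fold of 2, each library left out in turn, camera with an estimated correlation, fry, and a prior count of 0.5 for the correlation. A run with protein-coding genes only was added after the values were seen. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Reads were not analysed here, nor was any sample-level clinical detail.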

Results

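Messenger RNA was measured by 3' end sequencing in 14 libraries of human myeloid cells from patients with non-small lung cancer. Monocytic myeloid-derived suppressor cells (M-MDSC), monocyte-like cells known for restraining T cells, and monocytes came from the same 3 patients (n = 3 libraries each). Macrophages derived from M-MDSC and macrophages derived from monocytes came from 4 other patients, who gave both (n = 4 libraries each). Depth per library was 13624702, 15259182 and 13965260 counts for M-MDSC and 15514810, 14746704 and 15285623 for monocytes. It was 17423563, 23624591, 24248180 and 26412473 for M-MDSC-derived macrophages and 24463088, 22006520, 24931555 and 25483123 for monocyte-derived macrophages. Each library held between 18361 and 19234 genes with at least 1 count, and 18543 genes were tested. Levels are mean CPM, counts scaled to the size of the library, ± SD over libraries, and fold changes are log2 values ± SE. Intervals on ratios and floors for groups without counts cover counting error only. Across genes, which are not independent of one another, log2 levels of 2 libraries correlated at 0.974 to 0.979 within each macrophage group and at 0.636 to 0.675 between source cells and macrophages.

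The first comparison asked how M-MDSC differed from the monocytes of the same patients (3 libraries against 3). Genes that display peptides to helper T cells were lower in M-MDSC: 5 of the 15 class II antigen presentation genes tested fell, 10 did not pass, and 9 fell when adjusted over the list alone. HLA-DPB1, a chain of the class II molecule HLA-DP, averaged 75.0 ± 35.0 CPM in M-MDSC and 724 ± 49.4 in monocytes (log2 fold change -3.27 ± 0.30, edgeR adjusted p = 0.00022). Its partner HLA-DPA1 averaged 75.0 ± 37.3 against 802 ± 183 CPM (-3.42 ± 0.45, edgeR adjusted p = 0.00392). HLA-DRA, the chain of HLA-DR that is commonly stained to tell M-MDSC from monocytes, fell by 2.30 ± 0.37 (edgeR adjusted p = 0.0104). Whether these cells were sorted on HLA-DR is not given, and such a sort could by itself set lower class II levels. HLA-DMA, which helps load peptides, fell by 1.64 ± 0.29 (edgeR adjusted p = 0.0131). The class II list had a median log2 fold change of -1.81 and was lower against all other genes (camera adjusted p = 1.13e-20, and 0.00427 with an estimated correlation). C1QA, a complement subunit that helps clear dying cells, averaged 0.366 ± 0.577 CPM against 34.7 ± 12.7 (-6.48 ± 0.77, edgeR adjusted p = 0.00330). Its partner C1QB had 0 counts in M-MDSC against 4.97 ± 1.67 CPM in monocytes, at least 81.4-fold lower. FCGR3A, the Fc receptor CD16 that marks non-classical monocytes, averaged 23.6 ± 13.4 CPM against 299.5 ± 152 (-3.67 ± 0.53). CDKN1C, a cell-cycle inhibitor abundant in the same subset, averaged 12.1 ± 8.29 against 95.1 ± 37.4 (-2.97 ± 0.59). Reads of FCGR3A are uncertain because FCGR3B is a near-identical copy, and those of class II genes because their alleles differ.

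The other largest falls were those of ATP1B1, a sodium pump subunit (-3.97 ± 0.38, edgeR adjusted p = 0.00022), and SASH1, a signalling scaffold (-2.95 ± 0.33). MTSS1, which bends membranes at the cell edge (-3.03 ± 0.63), NEURL1, a ubiquitin ligase (-3.57 ± 0.67), and TMEM51, a membrane protein of little known function (-3.69 ± 0.53), followed. Of 33 macrophage maturation genes, 2 fell, the complement genes C1QA and C1QB, while 7 fell and 1 rose when adjusted over the list alone. This list was lower (camera adjusted p = 3.11e-06, adjusted p = 0.0894 with an estimated correlation, and 0.0418 with a block for the patient as well). Dendritic-cell markers were lower as a list too (camera adjusted p = 0.000934, and 0.0320 with an estimated correlation), a call lost at that correlation with a block for the patient (adjusted p = 0.0754), with 0 of 12 passing and 4 falling when adjusted over the list alone. With a block for the patient 4 of the dendritic-cell markers fell. The lectin CLEC10A, one of these markers, averaged 1.92 ± 1.71 CPM in M-MDSC and 23.1 ± 4.32 in monocytes.

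Of 10 S100 genes, whose products bind calcium and act as inflammatory alarm signals, 2 rose in M-MDSC, and 4 did when adjusted over the list alone. The list had a median of 0.13 and was higher with the preset correlation (camera adjusted p = 0.000222, adjusted p = 0.173 with an estimated correlation). S100A12 averaged 664 ± 159 CPM against 153 ± 52.1 in monocytes (2.12 ± 0.38, edgeR adjusted p = 0.0202). S100P averaged 54.4 ± 4.36 against 7.55 ± 3.69 CPM (2.85 ± 0.49, edgeR adjusted p = 0.0128). S100A8 and S100A9 pair up as calprotectin and mark suppressor cells in many tumors. They averaged 6252 ± 1782 against 1937 ± 874 CPM (1.69 ± 0.41) and 2640 ± 773 against 933 ± 505 CPM (1.502 ± 0.39), and neither passed (edgeR adjusted p = 0.0849 and 0.0999). With a block for the patient both did (1.78, edgeR adjusted p = 0.000602, and 1.67, edgeR adjusted p = 0.00311).

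PADI4, the enzyme that citrullinates histones in neutrophil traps, averaged 79.4 ± 31.2 CPM against 8.41 ± 5.62 (3.24 ± 0.53, edgeR adjusted p = 0.0117). MGAM, a sugar-cleaving enzyme made by neutrophils, averaged 20.8 ± 12.3 CPM against 0.551 ± 0.433 (5.20 ± 0.86). MGAM was the only one of 16 neutrophil markers to rise, while 11 rose when adjusted over the list alone. The neutrophil list was higher (camera adjusted p = 2.22e-10, and 0.000789 with an estimated correlation). CYP1B1, a hydrocarbon-metabolizing enzyme, averaged 537 ± 170.1 CPM against 115 ± 9.08 (2.23 ± 0.36). The remaining large rises were F5, clotting factor V (2.64 ± 0.51), TSPAN2, a tetraspanin (2.29 ± 0.44), and MTARC1, a mitochondrial reductase (2.25 ± 0.38). MCEMP1, a membrane protein of inflamed myeloid cells (2.07 ± 0.40), and WLS, which carries Wnt ligands to the surface (1.84 ± 0.34), completed them.

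Several other lists were lower in M-MDSC with the preset correlation of camera and lost that call with an estimated one in the fit without a block. Nuclear-encoded oxidative phosphorylation genes were negative in 30 of 32 (camera adjusted p = 0.000356, adjusted p = 0.415 with an estimated correlation). Interferon-stimulated genes were negative in 30 of 35 (camera adjusted p = 0.00142, adjusted p = 0.502 with an estimated correlation), and 0 genes of either list passed. With a block for the patient 4 oxidative phosphorylation and 8 interferon-stimulated genes fell, and 0 of either rose. Cholesterol genes were lower (camera adjusted p = 0.0260, adjusted p = 0.415 with an estimated correlation), as were myeloid transcription factors (camera adjusted p = 0.00033, adjusted p = 0.114 with an estimated correlation, and 0.0495 with a block for the patient as well). Among the factors 2 of 27 fell: NR4A1, which keeps non-classical monocytes alive (-1.90 ± 0.41), and RUNX3, which controls lymphocyte and dendritic-cell genes (-1.05 ± 0.21). NR4A1 was also the only one of 21 immediate early genes to fall, and 3 did when adjusted over the list alone (camera adjusted p = 0.00474, adjusted p = 0.261 with an estimated correlation). B-cell markers were lower with 0 of 11 passing (camera adjusted p = 0.00436, adjusted p = 0.191 with an estimated correlation).

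Immune suppression genes were not shifted as a list in 1 direction (camera adjusted p = 0.756): 0 of 24 passed, and 1 rose when adjusted over the list alone. With a block for the patient 2 rose and 4 fell, a split that a test for a shift in 1 direction cannot see. ENTPD1, which breaks down extracellular ATP, had 0.60 ± 0.14. Single genes passed in lists that did not. Among blood monocyte markers the integrin ITGAM rose by 0.95 ± 0.20 and FCGR3A, given above, fell. With a block for the patient 6 of these markers rose and 3 fell, so the list moved in both directions. The hexokinase HK2 rose by 0.81 ± 0.18 among glycolysis genes, and the cholesterol carrier NPC2 fell by 0.81 ± 0.17 among lysosomal genes. Camera adjusted p was 0.719, 0.175 and 0.876 for these 3 lists. Granule proteins of neutrophil precursors (camera adjusted p = 0.224, but 0.0204 and higher with a block for the patient, 0.275 with an estimated correlation), inflammatory cytokines (0.740), lipid efflux (0.318) and cell-cycle genes (0.196) did not pass. Markers of T cells (camera adjusted p = 0.740), NK cells (0.797), platelets (0.679) and epithelial cells with fibroblasts (0.185) did not pass either. Erythroid markers (4 tested) and eosinophil, basophil and mast-cell markers (2 tested) were too few to test as lists, and 0 of them passed.

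In total 143 of 18543 genes passed between M-MDSC and monocytes, 55 higher and 88 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 116 of them by at least 2-fold. Of 28 lists 14 were shifted, 2 higher and 12 lower, 3 with an estimated correlation and 7 without replicate 3 of M-MDSC. With a block for the patient 1207 genes passed, among them all 143, DESeq2 gave 628, a fit of these 6 libraries alone gave 48, and without replicate 3 of the monocytes 87 passed. Without a patient term modest effects go undetected: on simulated data, among genes with a mean of at least 5 CPM, the test found 28% of the 2-fold and 80% of the 4-fold changes, and with the block 71% and 94%.

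**Figure D1:**
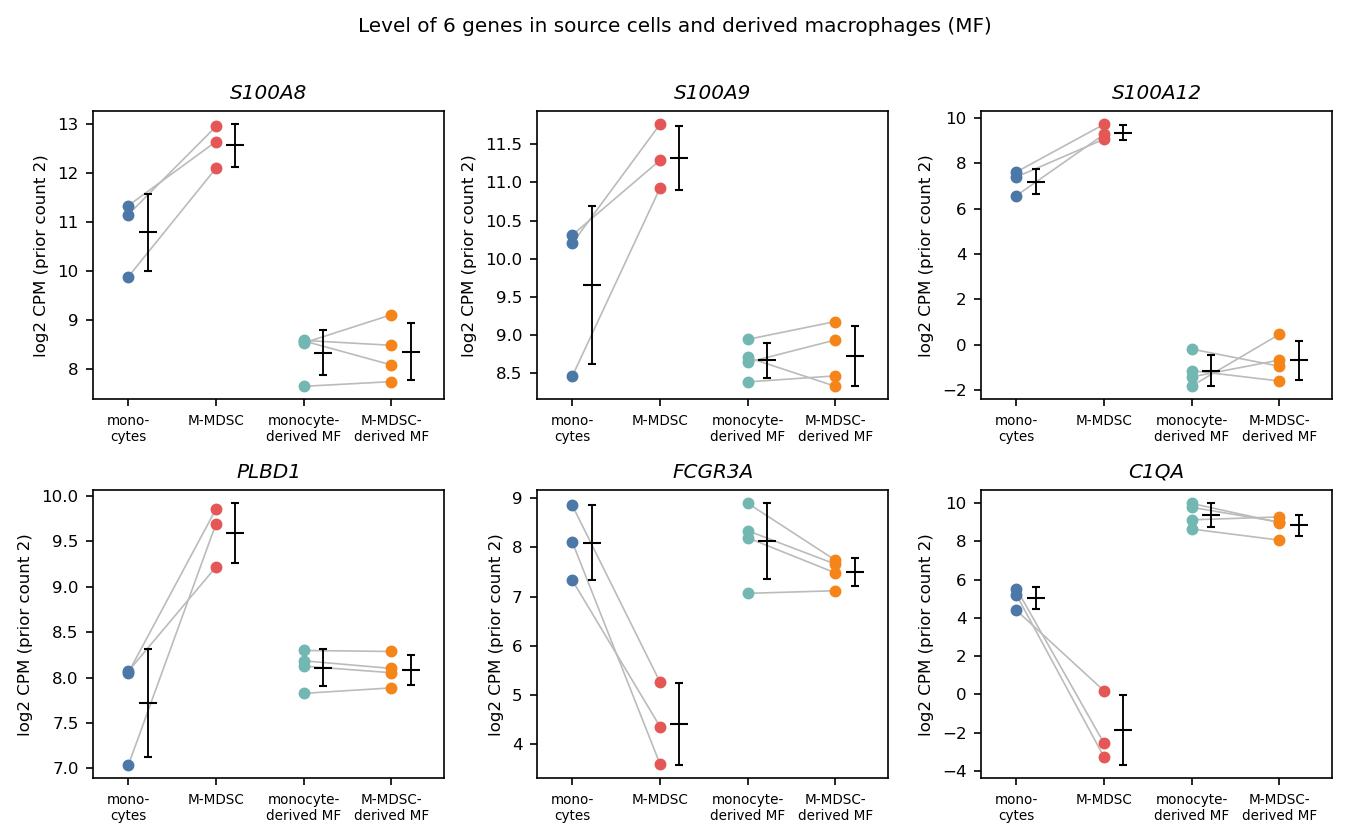
Level of 6 genes (y axis, log2 CPM with a prior count of 2) in each library of the 4 groups (x axis, n = 3, 3, 4 and 4); grey lines join libraries of the same patient, and black bars show the mean ± SD. S100A12 stood 2.12 log2 units higher in M-MDSC than in monocytes and 0.54 apart between the macrophages.

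The second comparison asked whether macrophages derived from M-MDSC differed from macrophages derived from monocytes of the same patients (4 libraries against 4). S100A9 and S100A8 were nearly level in the derived cells. S100A9 averaged 435 ± 120 CPM in M-MDSC-derived and 410.2 ± 64.9 in monocyte-derived macrophages (0.08 ± 0.33), S100A8 348 ± 148 against 333 ± 89.0 (0.06 ± 0.35), and S100A12 0.604 ± 0.455 against 0.390 ± 0.261 (0.54 ± 0.55). S100P, which rose in M-MDSC, averaged 13.04 ± 4.22 CPM against 7.07 ± 3.34 (0.88 ± 0.40), the largest S100 difference named here. The class II gene HLA-DPB1 averaged 230.4 ± 46.9 CPM against 306 ± 64.6 (-0.41 ± 0.24) and the complement gene C1QB 41.5 ± 16.1 against 88.6 ± 51.7 (-1.10 ± 0.41). CD163, a scavenger receptor of alternatively activated macrophages, averaged 103 ± 34.4 CPM against 152 ± 82.6 (-0.55 ± 0.35). IL4I1, an amino-acid oxidase that restrains T cells, averaged 23.8 ± 7.81 CPM against 52.7 ± 31.2 (-1.14 ± 0.53). MKI67, a marker of dividing cells, averaged 186 ± 65.9 CPM against 150.1 ± 47.6 (0.31 ± 0.25). None of these genes passed (edgeR adjusted p = 1 for each).

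Between the macrophages 0 genes of any list passed even when adjusted over the list alone, while 8 lists passed camera at its preset correlation. Class II genes were negative in 15 of 15 with a median of -0.25 (camera adjusted p = 0.000633, adjusted p = 0.688 with an estimated correlation). Interferon-stimulated genes were negative in 31 of 35 (camera adjusted p = 1.65e-05, adjusted p = 0.722 with an estimated correlation). Macrophage maturation genes were negative in 24 of 33 (camera adjusted p = 0.00287, adjusted p = 0.688 with an estimated correlation, and 0.0156 with a block for the patient as well). Cell-cycle genes were positive in 29 of 30 with a median of 0.14 (camera adjusted p = 0.000128, adjusted p = 0.774 with an estimated correlation). Neutrophil markers were higher, 10 positive and 5 negative (camera adjusted p = 0.0235, adjusted p = 0.369 with an estimated correlation). Ribosomal protein genes (camera adjusted p = 0.000342, adjusted p = 0.774 with an estimated correlation), myeloid transcription factors (camera adjusted p = 0.0281, 0.688 with an estimated correlation) and T-cell markers (camera adjusted p = 0.0286, 0.688 with an estimated correlation, and 0.0732 with a block for the patient) were lower, T-cell markers with 5 positive and 14 negative. S100 genes (camera adjusted p = 0.284) and immune suppression genes (0.538) were not shifted.

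Between the macrophages 0 of 18543 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), and 0 passed with a block for the patient. An unadjusted p under 0.05 was reached by 223 genes without the block and by 453 with it. Both are fewer than the 5% of genes that chance alone would give, so the test may be conservative here. Common biological variation was 29.3% without the block and 13% with it, so leaving the patient out hides differences. DESeq2 called 1, an unnamed gene (ENSG00000255107) with counts in 1 of 4 M-MDSC-derived libraries and 0 of 4 others, named here after its value was seen. The 10 genes of smallest p did not pass. Among them were TCF4, a transcription factor of plasmacytoid dendritic cells (23.3 ± 6.04 against 45.9 ± 17.1 CPM, -0.98 ± 0.26), and DPH1, which modifies the translation factor EF2 (2.95 ± 2.56 against 0.179 ± 0.219 CPM). The others, each under 1 CPM, were CFAP92, RUNX2, RAB3B, RBAK-RBAKDN, CABP4, LINC02913, LINC02473 and ENSG00000263120. The 8 shifted lists of 28, 2 higher and 6 lower, came to 0 with fry, and to 0 with an estimated correlation (macrophage maturation alone passed when a block for the patient was added) and to 4 without replicate 4 of the monocyte-derived macrophages. On simulated data this comparison found 58% of the 2-fold and 85% of the 4-fold changes, among genes with a mean of at least 5 CPM.

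**Figure D2:**
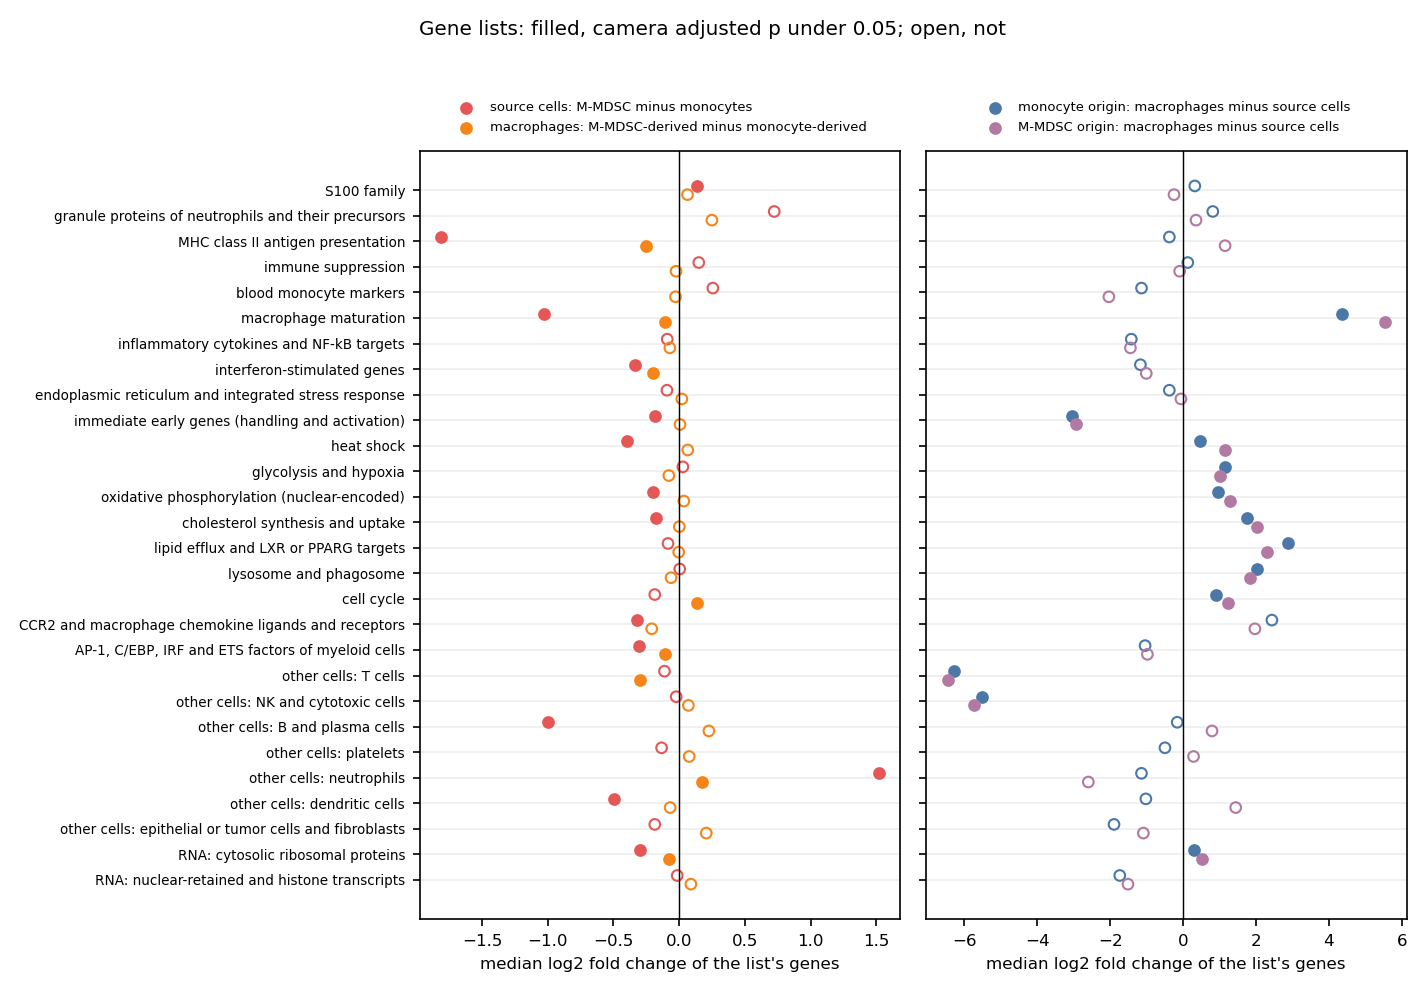
Median log2 fold change (x axis) of 28 gene lists (y axis) between origins (left) and between stages (right); filled points passed camera with the preset correlation (adjusted p under 0.05). Class II genes had a median of -1.81 in source cells and -0.25 in macrophages.

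The next 2 comparisons asked what differed between macrophages and source cells, for the monocyte origin (4 libraries against 3) and the M-MDSC origin (4 against 3). Among the largest rises were the lipid-carrier genes APOC1, APOE and APOC2, absent or nearly so in source cells. APOC1, an apolipoprotein, averaged 5922 ± 2855 CPM in monocyte-derived macrophages against 0.0200 in monocytes, a ratio of 296400 (95% counting interval 55560 to 12230000). In M-MDSC-derived macrophages it averaged 5469 ± 2628 CPM against 0, at least 89540-fold higher. APOE, which carries cholesterol out of cells, rose by 12.26 ± 0.88 (to 2587 ± 535 CPM) and by at least 40220-fold (to 2457 ± 622 CPM). Its neighbor APOC2 rose by at least 4043-fold and 3875-fold. CHI3L1, a secreted chitinase-like protein, rose to 5215 ± 1430 and 5435 ± 1418 CPM, and TIMP3, a protease inhibitor, to 796 ± 337 and 733 ± 272 CPM. In the monocyte origin the chitinase CHIT1 rose to 2682 ± 1559 CPM and the matrix protease MMP7 to 939.9 ± 456 CPM, and in the M-MDSC origin SPP1, osteopontin, rose to 2136 ± 922 CPM. Further large rises from 0 counts were GAL, a neuropeptide (at least 7353-fold and 6795-fold), and NUPR1, a stress-response regulator (at least 5535-fold and 3519-fold). BHLHE41, a repressor that governs macrophage identity, rose by at least 3936-fold and 4331-fold. TM4SF19, a tetraspan protein, rose by at least 12800-fold and EPB41L1, a cytoskeletal protein, by at least 4489-fold in the monocyte origin, and A2M, another protease inhibitor, by at least 13430-fold in the M-MDSC origin. Genes given for 1 origin were among the 10 largest rises there alone, and all of them passed in both.

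Of 33 macrophage maturation genes, 29 rose and 3 fell in each origin, among them GPNMB, a lysosomal glycoprotein (7.74 ± 0.43 and 7.60 ± 0.43), and the acid phosphatase ACP5 (5.82 ± 0.31 and 6.996 ± 0.33). This list was higher in the monocyte origin (camera adjusted p = 2.79e-12, adjusted p = 0.0569 with an estimated correlation) and in the M-MDSC origin (camera adjusted p = 6.12e-13, and 0.0283 with an estimated correlation). Lipid efflux genes rose in 11 and 12 of 15, such as the fatty-acid desaturase SCD (5.56 ± 0.23 and 5.66 ± 0.23), while MYLIP, which degrades the LDL receptor, fell (-2.77 ± 0.26 and -3.20 ± 0.26). That list was higher in both (camera adjusted p = 8.18e-05 and 0.000151, and 0.0326 and 0.0283 with an estimated correlation). Lysosomal genes rose in 25 of 28 in each origin, such as the protease CTSD (9977 ± 2327 against 713 ± 240.2 CPM in the monocyte origin) and the cholesterol exporter NPC1 (2.89 ± 0.21 and 2.91 ± 0.22). Cholesterol genes rose in 14 and 15 of 18. Oxidative phosphorylation genes rose in 27 and 30 of 32, such as the respiratory subunit NDUFA4 (2.53 ± 0.19 and 3.08 ± 0.20). Glycolysis genes rose in 17 and 16 of 25, such as the pyruvate kinase PKM (3.61 ± 0.15 and 3.22 ± 0.15). Cell-cycle genes rose in 21 and 24 of 30, MKI67 among them (2.18 ± 0.29 and 2.79 ± 0.30). These 5 lists were higher in both origins, with camera adjusted p = 5.35e-11, 2.46e-06, 7.24e-08, 3.77e-05 and 0.00407 in the monocyte origin and 1.30e-09, 4.45e-07, 1.30e-09, 0.000734 and 0.000398 in the M-MDSC origin. All lost that call, with adjusted p = 0.116, 0.116, 0.269, 0.230 and 0.716, and 0.141, 0.119, 0.165, 0.328 and 0.575, with an estimated correlation.

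Genes switched on within minutes of a stimulus were lower in macrophages: 16 of 21 immediate early genes fell in each origin. The AP-1 subunit FOS averaged 11.4 ± 4.59 CPM in monocyte-derived macrophages against 887 ± 269.9 in monocytes, and the nuclear receptor NR4A2 had -8.05 ± 0.38 and -8.92 ± 0.41. Markers of T cells fell in 19 of 21 in each origin, and markers of NK and cytotoxic cells in 13 and 12 of 15. GNLY, a pore-forming protein of killer lymphocytes, averaged 141 ± 7.87 CPM in M-MDSC. It had 0 counts in M-MDSC-derived macrophages, which came from other patients, at least 3911-fold lower. The killer protease GZMA was at least 2961-fold lower. The T-cell and NK-cell lists mark cells of other types, so lymphocytes in the source libraries could hold these transcripts. The immediate early list was fixed as a sign of handling and activation. Neither cause was tested. The immediate early, T-cell and NK-cell lists were lower in the monocyte origin (camera adjusted p = 9.41e-08, 5.50e-08 and 9.75e-06, adjusted p = 0.0820, 0.0814 and 0.0852 with an estimated correlation). They were also lower in the M-MDSC origin (camera adjusted p = 5.12e-06, 1.20e-07 and 4.04e-05, adjusted p = 0.119, 0.0394 and 0.119 with an estimated correlation). S100A9 fell by 1.18 ± 0.35 in the monocyte origin (edgeR adjusted p = 0.00909) and fell by 2.60 ± 0.36 in the M-MDSC origin (edgeR adjusted p = 2.25e-05). S100A8 fell too (-2.54 ± 0.38 and -4.17 ± 0.40), as did S100A12 (-8.59 ± 0.49 and -10.17 ± 0.50). Blood monocyte markers fell in 10 and 11 of 18, while the list did not pass (camera adjusted p = 0.142 and 0.114).

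The class II gene HLA-DPB1 fell by 1.24 ± 0.26 in the monocyte origin and rose by 1.62 ± 0.27 in the M-MDSC origin. Of 15 class II genes 2 rose and 3 fell in the monocyte origin, 9 rose and 1 fell in the M-MDSC origin, and the list passed in neither (camera adjusted p = 0.898 and 0.0735). The largest falls of all were EHBP1-AS1, an antisense RNA (505 ± 179 and 442 ± 224 CPM in source cells), and SHANK2-AS3, another one (at least 1587-fold and 1684-fold). The protease ADAM19 fell by at least 1674-fold and 2411-fold, and FAM184B, of unknown function, by at least 3055-fold in the monocyte origin. Copies of the 7SL RNA, such as RN7SL202P and RN7SL744P (at least 1543-fold and 1359-fold, monocyte origin), and unnamed genes made up the rest.

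In total 12106 genes passed in the monocyte origin, 5246 higher (43.3%) and 6860 lower, and 12420 in the M-MDSC origin, 5474 higher (44.1%) and 6946 lower (edgeR quasi-likelihood test, Benjamini-Hochberg). By at least 2-fold 9679 and 10010 did so, and 12 of 28 lists were shifted in each, 9 higher and 3 lower. With an estimated correlation 1 list remained in the monocyte and 3 in the M-MDSC origin. Scaled by library totals alone, the higher share was 33.1% and 34.8% and the median log2 fold change of all genes -0.53 in each, against -0.18 and -0.20. The 2 stages share 0 patients, and log2 levels of libraries of different patients correlated at 0.899 or more within a stage and at 0.636 to 0.675 between stages.

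A further comparison asked for which genes the difference between origins itself differed between macrophages and source cells (macrophage difference minus source difference, 4 groups). ATP1B1, the sodium pump subunit, had -3.97 ± 0.38 between the source cells and 0.02 ± 0.26 between the macrophages, a difference of 3.99 ± 0.45 (edgeR adjusted p = 0.00454). The class II gene HLA-DPB1 had a difference of 2.86 ± 0.37 (edgeR adjusted p = 0.0109), the complement gene C1QA 5.90 ± 0.88, and RHOC, a regulator of cell movement, 2.44 ± 0.34. Differences above 5 log2 units were also those of DOCK1, which helps engulf dying cells (5.50 ± 0.78), DAGLA, a lipase that makes an endocannabinoid (5.38 ± 0.73), and the adhesion protein SORBS3 (5.30 ± 0.78). VASH1, an inhibitor of vessel growth (1.83 ± 0.31), and the unnamed ENSG00000271882 (7.07 ± 1.07) had positive differences too, as did LYNX1, a receptor modulator (6.95 ± 1.04), named after the values were seen because it lay under 10 CPM. PLBD1, a phospholipase of monocytes and neutrophils, was the 1 gene with a negative difference (-1.85 ± 0.32, edgeR adjusted p = 0.0499), and this call was lost with robust=FALSE and without any 1 of the 8 macrophage libraries (0 negative genes in each), or 1 of 3 of the 6 source libraries. It averaged 783 ± 169.7 CPM in M-MDSC against 222 ± 78.5 in monocytes and 272 ± 31.2 against 278 ± 37.1 in the macrophages. S100A9 had -1.42 ± 0.50 and did not pass (edgeR adjusted p = 0.498, and 0.0275 with a block for the patient). Neither did S100A12 (-1.58 ± 0.68, edgeR adjusted p = 0.616).

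Class II genes as a list were higher for this difference, with 1 of 15 passing and 6 rising when adjusted over the list alone (camera adjusted p = 2.10e-15, and 0.0136 with an estimated correlation). Neutrophil markers were lower, with 3 of 16 falling when adjusted over the list alone (camera adjusted p = 2.63e-07, and 0.00354 with an estimated correlation). Dendritic-cell markers were higher (camera adjusted p = 0.00165, and 0.0370 with an estimated correlation), as were macrophage maturation genes (camera adjusted p = 0.000117, adjusted p = 0.174 with an estimated correlation). With a block for the patient the class II, neutrophil and dendritic-cell lists no longer passed at an estimated correlation (adjusted p = 0.0913, 0.0611 and 0.148). The S100 list was lower (camera adjusted p = 0.00245, adjusted p = 0.318 with an estimated correlation). In total 11 genes passed, 10 positive and 1 negative (edgeR quasi-likelihood test, Benjamini-Hochberg), and 15 of 28 lists were shifted, 4 with an estimated correlation and 0 when the block was added to it. The balance was nearer to even with the block for the patient (442 genes, 265 positive and 177 negative) and with DESeq2 (154 genes, 93 positive and 61 negative), and no filter on low counts gave 19. Without 1 library the count ran from 7 (leaving out replicate 1 or 2 of the M-MDSC-derived or replicate 1 of the monocyte-derived macrophages) to 18 (leaving out replicate 3 of the monocytes).

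The last comparison asked whether the difference between origins ran the same way in source cells and in macrophages. The 2 differences came from different patients, so no cells were followed from one stage to the other. Across 18543 genes, which are not independent of one another, the mean patient log2 difference of source cells and that of macrophages correlated at r = 0.039. The exact sign-flip p was 0.0313, the smallest that 128 patterns allow, and the highest other |r| was 0.033. By rank the correlation was 0.013 (exact sign-flip p = 0.656). Over the 143 genes that passed in source cells, r was 0.549 and 98 (68.5%) kept their sign, which 4 of 16 sign-flip patterns reached. Their median absolute log2 difference was 1.90 in source cells and 0.12 in macrophages. HLA-DPB1 showed this shape, with -3.27 ± 0.30 and -0.41 ± 0.24. The 95% interval in macrophages lay closer to 0 than the source effect for 141 of the 143. These genes were chosen by their source values, which makes the source effects look larger, and the error of the source effect was left out.

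**Figure D3:**
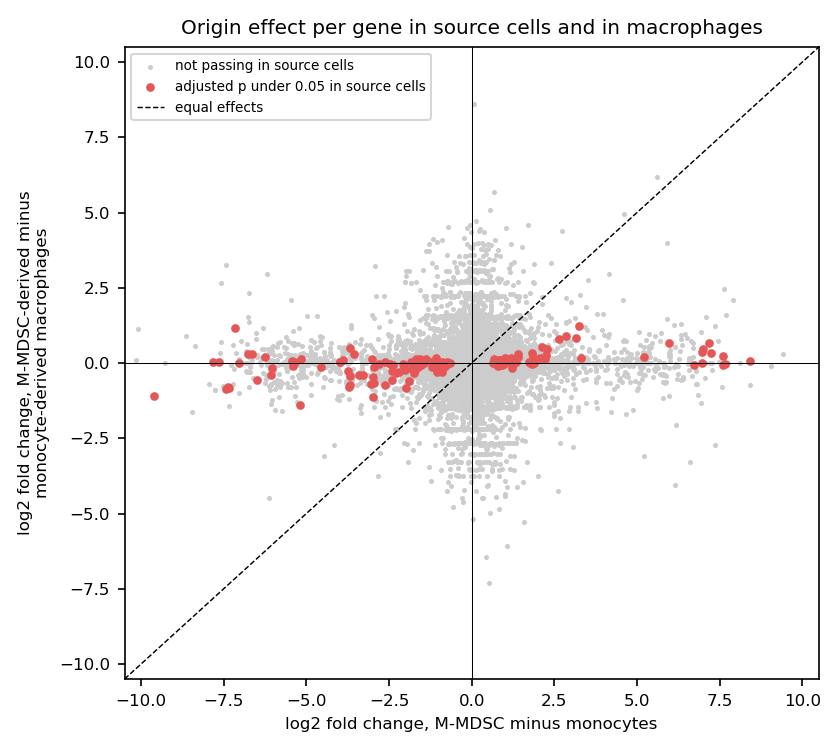
Log2 fold change of each of 18543 genes between origins in source cells (x axis) and in macrophages (y axis); red points passed in source cells (143 genes), and the dashed line marks equal effects. The red points lie near the x axis, with a median absolute value of 1.90 on the x axis and 0.12 on the y axis. They were chosen by their x values, so part of this gap is built in.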

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

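The tests of further non-classical markers, of neutrophil transcripts, of counts outside protein-coding genes and of protein-coding genes alone were chosen only after the results were seen, and the other tests were planned. Of 174 groups of 4 libraries screened, 5 (2.9%) had 1 library far from the other 3 (Dixon's test, which flags 1 in 20 by chance). In monocyte-derived macrophages these were S100A8 at 199.5 CPM (others 369 to 383), GPNMB at 4460 CPM (others 2616 to 2828) and RHOC at 137 CPM (others 153 to 154). In M-MDSC-derived macrophages they were TCF4 at 14.3 CPM (others 25.4 to 27.2) and SASH1 at 23.7 CPM (others 12.3 to 14.1).

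The difference between origins itself differed between macrophages and source cells for 11 genes. Its log2 size was 3.99 for ATP1B1, 2.86 for HLA-DPB1, 5.90 for C1QA, 2.44 for RHOC, 1.83 for VASH1 and -1.85 for PLBD1. It was 5.30 for SORBS3, 5.38 for DAGLA, 5.50 for DOCK1, 6.95 for LYNX1 and 7.07 for ENSG00000271882.

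A smaller share of non-classical monocytes in the M-MDSC libraries could explain the falls of FCGR3A, CDKN1C and class II genes. The 12 further markers of that subset, not named above, had a median of -0.97, with 11 negative. Their list was drawn up after the results were seen, so it is not an independent check. Class II genes had a median of -2.20, lower than that of all non-classical markers (FCGR3A and CDKN1C included) by -0.896, so whether class II genes fell with the subset or further cannot be told from it. All 23 classical markers tested were positive (median 1.02), with 4 passing, and 16 with a block for the patient. The list held genes already named as higher (S100A8, S100A9, S100A12, PADI4, MCEMP1 and PLBD1), the 4 that passed among them, so it is partly drawn from these values. Loss of another subset may contribute. It would raise each by 1 factor only if that subset held none of these transcripts, which was not tested. S100A12 rose by 1.601 more than the median of CD14, VCAN, FCN1 and LYZ. That gap was judged by the error of S100A12 alone and cannot decide the question. Neutrophils in the M-MDSC libraries remain a possible source of the rises of S100A12, PADI4 and MGAM. The 8 tested transcripts abundant in neutrophils and scarce in monocytes had a median of 1.24, with 0 passing, and 3 with a block for the patient. All of them belonged to the neutrophil list already tested. Higher in M-MDSC were, among others, CMTM2 (14.1 against 1.83 CPM), CXCR2 (15.1 against 7.72 CPM) and CXCR1 (0.602 against 0 CPM), although KRT23 (0.715 against 0.630 CPM) and the receptor FCGR3B (1.60 against 2.06 CPM) hardly differed. Subset share, neutrophils, a sort on low HLA-DR and a change within each cell cannot be told apart without the sort, which is not given in the sources used here.

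Counts outside protein-coding genes made up 8.24% to 9.51% of source libraries and 2.73% to 3.28% of macrophage libraries, a gap of at least 4.96 points that a different RNA input or library make-up may explain. Within them 7SL and Y RNA genes had medians of -6.74 in the monocyte and -7.01 in the M-MDSC origin. When protein-coding genes alone were tested and scaled, 64% of them passed in the origin with fewer, so the other counts do not make up the calls, but a difference of RNA input that also reaches protein-coding genes remains possible. Other patients alone do not make up the difference between stages, since libraries of different patients correlated at 0.899 or more within a stage and at 0.675 at most between stages. A part from other patients and library batch, which no label names, stays open because 0 patients have libraries of both stages.

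Low power for effects of the size fitted in source cells is an unlikely reason for 0 genes between the macrophages: for 141 of the 143 source genes the 95% interval in macrophages lay closer to 0 than the source effect, and for 123 it lay under 0.5 of it. The 143 were chosen by their source values, which makes those effects look larger, and the error of the source effect was left out. How far their true source effects exceed those in macrophages cannot be told from these counts. The median interval reached 0.57 log2 units to each side, so smaller effects may have been missed. With a block for the patient it reached 0.28 over the 1207 source genes that passed with it, and lay closer to 0 for 1192 of them. Whether other patients would have kept the difference cannot be told, since 0 patients gave both stages.

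The libraries of each comparison were also divided in every other way into groups of the same sizes, or in 100 drawn ways of 700 for the difference of the origin effect. For source cells the labelled division gave 143 genes and 14 lists and the highest other division 67 genes and 13 lists; 1 of 10 divisions reached each, and 10 are too few for a share under 0.05. Those that part every patient pair gave at most 3 genes. Between macrophages a count of 0 is reached by all 35 divisions by construction and says nothing on chance. The divisions that kept both libraries of every patient together, and so set patients against patients, gave 43, 36 and 7 genes. This points to differences between patients. All other divisions gave at most 1, and the 8 that part every patient pair gave 0. The 8 lists were reached by 12 of 35 divisions (highest 13), so chance cannot be excluded. Between stages the labelled division gave the most genes (12106 against 5145, and 12420 against 5770), each reached by 1 of 35, the smallest share that 35 divisions allow. A division that mixes the stages puts their gap into the spread, and the median of the other divisions was 0 genes. The labelled division is thus favoured in advance, and its rank cannot decide on chance. Chance cannot be excluded for the 12 lists either, which 13 of 35 divisions reached in the monocyte origin (highest 14) and 14 of 35 in the M-MDSC origin (highest 15). For the difference of the origin effect 12 of 100 divisions reached 11 genes (highest 79) and 4 of 100 reached 15 lists (highest 16). Among the 9 that part every patient pair the highest other gave 47 genes and 16 lists, so chance cannot be excluded for either. Counts as high as 79 point to a structure of the samples, whose source was not tested.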

How the results depend on the processing

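Only the protein-coding run among these tests was chosen after the results were seen. No gene named for the stage comparisons turned direction, their counts ran from 8615 to 12591 in the monocyte and from 8929 to 12933 in the M-MDSC origin, and 0 genes passed between macrophages in every setting but DESeq2 (1 gene). Scaling, filtering, robust fits, thinning and protein-coding genes alone gave 135 to 161 genes between M-MDSC and monocytes, of which 123 to 139 were among the 143. Over all settings but leave-outs, 21 of 315 calls of named source genes weakened and 13 strengthened. A block for the patient gave 1207 there, 442 for the difference of the origin effect (11 without it) and 1.67 for S100A9 in source cells, which then passed. The same block brought CLEC10A (-3.91), ENTPD1 (0.60), HSPB1 (-1.44), HSPE1 (-0.65), CMTM2 (3.15), CXCR1 (without counts in monocytes, so no fold is given) and S100A8 (1.78) under the threshold in source cells and S100A9 (-1.61) for the difference, and changed no other call of a gene whose level or fold change is given for that comparison. As lists, granule proteins in source cells (camera adjusted p = 0.0204, 0.275 with an estimated correlation) and lysosomal genes between macrophages (0.00446, 0.207 with an estimated correlation) passed with it, and T-cell markers between macrophages (0.0732) did not. For the difference, granule proteins (0.0449, 0.373 with an estimated correlation) and interferon-stimulated genes (0.0349, 0.402 with an estimated correlation) passed with it and chemokine genes (0.0678) did not. DESeq2 gave 628 and 154 genes and 1.52 for S100A9, which passed with it. Fitting the 6 source libraries alone gave 48 genes (34 of the 143), and no filter on low counts gave 19 for the difference. With camera at an estimated correlation 3, 0, 1, 3 and 4 lists shifted (M-MDSC against monocytes, macrophages, monocyte origin, M-MDSC origin, difference), and with fry 8, 0, 24, 24 and 4, against 14, 8, 12, 12 and 15. The correlation of origin effects was 0.022 with a prior count of 0.5 and 0.065 with at least 5 CPM, against 0.039. At an estimated correlation the block added macrophage maturation between macrophages, and in source cells macrophage maturation and myeloid factors. It ended dendritic-cell markers there and all 4 lists of the difference, heat shock among them (0.133). For these changes the cause was not tested.

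With 1 library left out and no block for the patient, source-cell counts ran from 87 to 208, their lists from 7 to 15 and S100A9 from 1.10 to 1.78. With 1 patient left out and the block, counts ran from 862 to 1342 and S100A9 reached 2.01. The correlation ran from 0.023 to 0.049. Of 315 such calls of named source genes, 59 weakened and 21 strengthened. The difference of the origin effect ran from 7 to 18 genes and 9 to 16 lists, and the macrophage lists from 4 to 8. Between macrophages the fold changes near 0 turned sign: S100A9 ran from -0.084 to 0.214, S100A8 from -0.249 to 0.238, S100A12 from -0.225 to 1.233, ATP1B1 from -0.091 to 0.100 and PLBD1 from -0.116 to 0.038. Depth limits genes of few counts, and the smallest library held 13624702 counts.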

Other observations

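Heat-shock genes, which refold damaged proteins, were lower as a list in M-MDSC than in monocytes: 0 of 11 passed, all 11 were negative, and 3 fell when adjusted over the list alone (camera adjusted p = 0.000222, adjusted p = 0.0513 with an estimated correlation). With a block for the patient 4 of them fell. HSPB1, a small chaperone, averaged 8.69 ± 4.08 CPM in M-MDSC and 23.5 ± 11.1 in monocytes (-1.44 ± 0.36), and the mitochondrial chaperonin HSPE1 had -0.65 ± 0.15. In macrophages against source cells 6 of 11 rose in the monocyte and 8 in the M-MDSC origin, HSPB1 by 4.63 ± 0.39 and 6.02 ± 0.42 (camera adjusted p = 0.0251 and 0.00134, adjusted p = 0.222 and 0.119 with an estimated correlation). Genes of the endoplasmic reticulum stress response were shifted in none of these (camera adjusted p = 0.0923 in source cells, 0.959 and 0.684 between stages): 8 rose and 11 fell of 24 in the monocyte origin, with the stress factor ATF3 up by 2.79 ± 0.34 and PPP1R15A, which restores translation after stress, down (-2.30 ± 0.20). Ribosomal protein genes were lower in M-MDSC with 0 of 63 passing (camera adjusted p = 6.29e-10, adjusted p = 0.395 with an estimated correlation). With a block for the patient 17 of them fell in M-MDSC and 0 rose. In macrophages against source cells 26 and 35 rose, RPL3 by 2.93 ± 0.18 and 3.06 ± 0.19 (camera adjusted p = 0.00579 and 0.000151, adjusted p = 0.736 and 0.575 with an estimated correlation). Nuclear-retained and histone transcripts were not shifted in M-MDSC against monocytes (camera adjusted p = 0.719), and between stages 5 of 9 fell in each origin, the nuclear RNA MALAT1 among them (-2.43 ± 0.30 and -2.39 ± 0.30).

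Chemokine genes changed in opposite ways between stages: 8 of 13 rose and 4 fell in the monocyte origin, 7 and 4 in the M-MDSC origin. CCL22, which draws regulatory T cells, rose by 10.54 ± 0.82 and 10.46 ± 0.82, and CX3CR1, which non-classical monocytes use to patrol vessels, fell (-9.501 ± 1.06 and -8.88 ± 1.07). In source cells the chemokine list was lower in M-MDSC (camera adjusted p = 0.0345, adjusted p = 0.191 with an estimated correlation). Immune suppression genes also split between stages, 10 rising and 8 falling of 24 in the monocyte origin: LGALS1, a lectin that kills activated T cells, rose by 3.26 ± 0.26 and 3.35 ± 0.26, while PTGS2, which makes prostaglandin E2, fell (-5.003 ± 0.20 and -4.96 ± 0.20) and so did the checkpoint VSIR (-3.57 ± 0.33 and -3.75 ± 0.33). Among inflammatory genes 12 of 23 fell and 6 rose in each origin. The inflammasome sensor NLRP3 fell (-5.46 ± 0.40 and -5.66 ± 0.40), while the macrophage growth factor CSF1 rose by 4.07 ± 0.27 and 4.29 ± 0.28. Of interferon-stimulated genes 18 and 20 of 35 fell, such as the antiviral MX2 (-2.07 ± 0.24 and -2.42 ± 0.24), and 3 and 5 rose, such as IFI6 (2.84 ± 0.33 and 2.94 ± 0.33). Between stages none of the chemokine, immune suppression, inflammatory and interferon lists passed. Camera adjusted p was 0.333, 0.489, 0.313 and 0.158 in the monocyte origin and 0.215, 0.526, 0.301 and 0.301 in the M-MDSC origin.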
